A study of Mus musculus with 12 samples.

How the data were processed

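RNA from mouse embryo footpad skin was measured on 12 Agilent arrays, 2 for each of 6 groups formed by genotype (skin-specific beta-catenin knockout or wild type) and embryonic day (E15.5, E16.5 or E17.5). Per the labels, footpad RNA was labelled with Cy3 on every array and a common reference with Cy5, so dyes were not swapped. Per the labels' protocols, the reference mixed a universal mouse reference pool from cultured cell lines with RNA from a 129 embryonic stem cell line. Per the file headers, spots were read with Agilent Feature Extraction 9.5.1.1. The deposited array files hold spot intensity values and Agilent's log10 ratio of Cy5 over Cy3. The authors' series table holds processed values on a log10 scale. Differences between its columns correlated between 0.899 and 0.993, across spots, with differences between log ratios of footpad over reference, which gives its direction. Its columns matched the log10 ratio plus each spot's mean log10 reference level, and their medians lay between 2.556 and 2.588. How its 25030 spots were chosen is not given in the sources used here.

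Each array held 43451 spots, of which 1417 were controls. Mean intensities were corrected with the normexp method of limma 3.58.1 (R 4.3.3) with an offset of 50 and the median local background, and normalized by loess within each array with control spots at weight 0. Outlier spots were left out and saturated spots kept. Ratios were turned to log2 of footpad over reference, and spots of a probe were averaged. Of 42006 probes, 11638 were left out because Cy3 was well above background on fewer than 2 arrays, and 2 more because of outlier spots, which left 30366. The share of probe spots well above background in Cy3 ran from 59.0% to 72.3% per array. The number of arrays limits the precision.

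The files pair 0 of the probes with a gene symbol or a genome position, and no probe code matched the gene table used here. Results are therefore given per probe, by the manufacturer's code and its sequence of 60 bases. The gene lists, the cell type markers and the level of the targeted gene, which had been planned, were not analysed here, so the genotype labels were not checked against the targeted transcript. The planned mean over all probes of a gene was not run for the same reason. The rule for named items took, averaged over stages, the highest and lowest folds among probes with adjusted p under 0.05, at least 1.5-fold, whose knockout arrays lay on 1 side of the wild-type arrays at every stage. For each stage, the stage differences and the wild-type time course it took the highest and lowest folds among probes with adjusted p under 0.05 whose groups did not overlap. For the stage differences, knockout and wild type had to be apart at E15.5 or at E17.5, not at both. With no gene names, 2 probes per direction are named in each comparison in place of the longer lists the rule allowed. This rule, the groups, the tests and the main alternatives were fixed before the data were examined, but for genes with a symbol. The rule and tests were applied to probes afterwards.

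limma's moderated test was run on the means of the 6 groups, with 6 residual and 4.7 prior degrees of freedom and Benjamini-Hochberg adjustment. The contrasts were knockout against wild type at each stage, their mean, an F test of the difference between stages, and E17.5 against E15.5 in wild type. Probe classes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. These classes were chosen after seeing the data. For the class at least 4-fold over the reference, camera at the preset correlation also gave small p-values in arbitrary splits of the arrays. A probe not well above background on any array of a group has only a bound there, given as "at least" a fold against the lowest signal well above background, per channel after loess and Aquantile scaling, and open to dye bias. It is left out where it exceeds the fold of the ratios themselves. The labels do not say whether samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

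Each stage was hybridised on a slide of its own, and on every slide knockout samples lay at array positions 1 and 2 and wild type at 3 and 4. Stage and slide therefore cannot be told apart, and genotype is confounded with position. Knockout and wild-type samples share replicate numbers in the labels. Deviations of same-numbered samples from their group means correlated, across probes, at 0.61 at E15.5, 0.25 at E16.5 and 0.16 at E17.5. Each exceeded 0.1, so the numbers were taken to pair the samples, and blocked values are given where they move a count by over 1.5 times. Each value rests on 1 replicate difference per genotype, and deviations of arrays from different stages correlated by up to 0.38. That is above the values at E16.5 and E17.5, which therefore do not establish pairing. The blocked counts are an alternative to the main ones.

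The steps were tested on simulated data built from the levels and residual spread of the 30366 probes, with 200 probes changed. Of probes changed 1.5-fold, 61.2% were called at E15.5, 52.2% at E16.5, 52.2% at E17.5 and 88.1% in the average. For 2-fold changes the shares were 91.0%, 89.6%, 91.0% and 100%, and for 4-fold changes 98.5%, 98.5%, 100% and 100%. Unchanged probes called numbered 12, 2, 5 and 3 in the same order. The simulated noise was independent between arrays and had the same spread in every group. In the data, the SD of the difference between replicates ran from 0.132 in the E17.5 knockout to 0.302 in the E15.5 knockout. The shares therefore do not rank the stages and may not hold at E15.5. Alternatives covered the replicate block, Agilent's processed signals, an offset of 16, median centring, Aquantile scaling, Cy3 alone, 2 other filters, fits within a stage, array weights, each array left out, the authors' processed values, a 1.5-fold minimum, the reference channel alone and, chosen after seeing the data, a correction for probe GC content.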

Results

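Footpad skin, the site where mouse sweat glands form, was profiled in skin-specific beta-catenin knockout and wild-type embryos at E15.5, E16.5 and E17.5, with 2 arrays per genotype and stage. Beta-catenin carries the canonical Wnt signal, and the title of the study places the comparison in a series on Wnt, Eda and Shh in sweat gland development. Across the 30366 probes tested, log2 ratios of footpad over reference correlated between replicates from 0.9752 in the E15.5 knockout to 0.9951 in the E17.5 knockout. Cy3 was well above background at 65.3% of probe spots for wild-type replicate 1 at E15.5, against 59.0% to 59.4% on the other arrays of that stage. The leading principal component held 65.6% of the variance and separated E15.5 arrays, at -85.7 to -43.5, from E16.5 and E17.5 arrays, at 21.7 to 41.5.

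At E15.5, probe Z00008117-1 (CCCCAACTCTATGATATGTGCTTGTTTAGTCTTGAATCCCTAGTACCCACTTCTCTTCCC) was at least 6.27-fold lower in knockout, where it was not well above background on either array. Its log2 ratio was -0.24 ± 0.01 (SD, n = 2) in knockout and 2.63 ± 0.30 in wild type (limma adjusted p = 2.41e-05). Z00071877-1 (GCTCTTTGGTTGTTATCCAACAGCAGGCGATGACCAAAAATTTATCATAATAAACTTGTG) was lower by 5.92-fold, at 2.43 ± 0.25 against 4.99 ± 0.37 (log2 difference -2.57, limma adjusted p = 0.00219). That call was lost with Agilent's processed signals (log2 difference -2.10, limma adjusted p = 0.208, the highest of its alternatives, which began at 9.52e-05) and with the authors' processed values (-2.51, limma adjusted p = 0.0707), and Cy3 alone gave -1.80. Z00026847-1 (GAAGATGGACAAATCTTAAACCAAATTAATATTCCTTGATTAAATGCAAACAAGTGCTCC) was 3.38-fold higher in knockout, at 2.89 ± 0.16 against 1.13 ± 0.21 (limma adjusted p = 0.000301), with a log2 difference of 1.76 that was 2.59 with Agilent's processed signals. Z00051506-1 (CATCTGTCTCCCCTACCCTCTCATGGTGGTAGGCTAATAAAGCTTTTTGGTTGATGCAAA) was 3.36-fold higher, at 4.87 ± 0.04 against 3.12 ± 0.01 (limma adjusted p = 5.88e-05). In all, 915 probes were higher and 887 lower in knockout by limma's moderated test, with median folds of 1.44 and 1.53, and 6909 were called with the replicate block. A fit on the 4 arrays of this stage alone called 0 probes by limma, with 3744 at an unadjusted p under 0.05, and leaving out an array of this stage moved the count from 135 (without wild-type replicate 1) to 7809 (without knockout replicate 1). The split of calls depended on scaling, with 124 higher and 2324 lower under median centring, which moved the median of all probes to -0.11, and 224 higher and 457 lower with Agilent's processed signals. The stages share 1 estimate of each probe's spread, while replicates differed most in the E15.5 knockout (SD of the difference 0.302). Array weights reversed the order of the stages, with 243 calls at E15.5, 1096 at E16.5 and 2924 at E17.5. The counts therefore do not rank the stages.

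**Figure D1:**
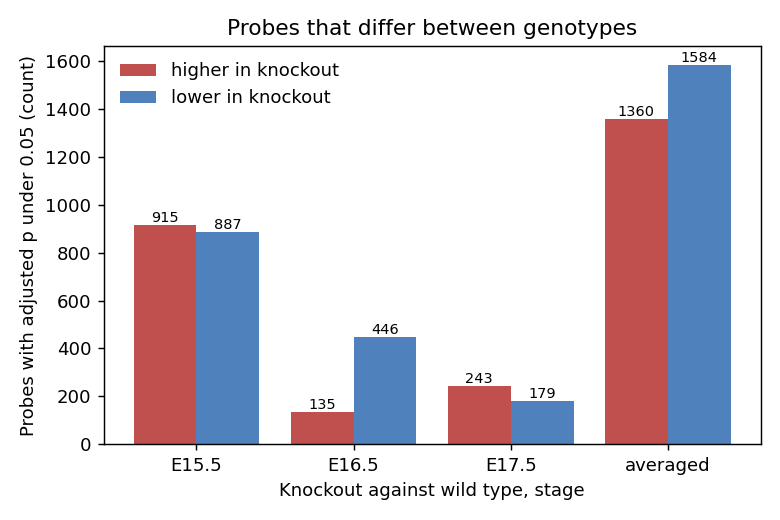
Number of probes (y axis) with an adjusted p under 0.05 in limma's moderated test of knockout against wild type at each stage and averaged over stages (x axis), red bars for probes higher in knockout and blue bars for probes lower. At E16.5, 446 probes were lower and 135 higher, while at E15.5 the split was 915 higher and 887 lower, a split that moved to 124 higher and 2324 lower under median centring. Array weights reversed the order of the stages by count, so the bars do not rank the stages.

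At E16.5, Z00008117-1 was again lower in knockout, by 8.84-fold, with a log2 ratio of 0.43 ± 0.13 (SD, n = 2) against 3.57 ± 0.10 in wild type (limma adjusted p = 8.99e-06). Z00028697-1 (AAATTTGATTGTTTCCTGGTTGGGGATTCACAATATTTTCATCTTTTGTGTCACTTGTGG) was 7.97-fold lower, at 1.11 ± 0.36 against 4.11 ± 0.26 (limma adjusted p = 0.00982). That call was lost without knockout replicate 2 (limma adjusted p = 0.122, the highest of its alternatives, which began at 0.000153), without wild-type replicate 1 (0.0603) and without wild-type replicate 2 of this stage (0.0503), with log2 differences of -2.74, -3.18 and -2.81 against -2.99, and Cy3 alone gave -2.38. Z00075857-1 (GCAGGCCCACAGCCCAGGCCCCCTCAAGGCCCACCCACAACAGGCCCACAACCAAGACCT) was 2.93-fold higher in knockout, at 0.52 ± 0.05 against -1.03 ± 0.01 (limma adjusted p = 0.00408), a call lost without knockout replicate 2 (log2 difference 1.51 against 1.55, limma adjusted p = 0.055, the highest of its alternatives, which began at 0.000805). Z00067154-1 (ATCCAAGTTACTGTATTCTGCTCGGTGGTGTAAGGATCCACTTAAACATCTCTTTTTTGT) was 2.73-fold higher, at 2.02 ± 0.06 against 0.57 ± 0.11 (limma adjusted p = 0.00416). In all, 135 probes were higher and 446 lower by limma's moderated test, with median folds of 1.48 and 1.59. The replicate block called 2378 probes, and leaving out knockout replicate 2 of this stage gave 115. Median centring called 85 higher and 123 lower, and with Agilent's processed signals Z00067154-1 missed the threshold with a log2 difference of 1.64 against 1.45 (limma adjusted p = 0.299, the highest of its alternatives, which began at 0.000463).

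At E17.5, Z00056369-1 (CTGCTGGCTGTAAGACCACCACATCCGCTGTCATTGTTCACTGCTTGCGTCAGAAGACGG) was 5.99-fold higher in knockout, with a log2 ratio of 3.58 ± 0.17 (SD, n = 2) against 1.00 ± 0.39 in wild type (limma adjusted p = 0.000199). Z00023605-1 (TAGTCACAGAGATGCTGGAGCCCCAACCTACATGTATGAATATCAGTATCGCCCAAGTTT) was 4.62-fold higher, at 2.18 ± 0.10 against -0.03 ± 0.03 (limma adjusted p = 2.17e-06), and its log2 difference of 2.21 was 3.18 with Agilent's processed signals. Z00068163-1 (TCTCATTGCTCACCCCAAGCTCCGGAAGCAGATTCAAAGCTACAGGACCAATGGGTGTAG) was 6.15-fold lower in knockout, at -0.41 ± 0.03 against 2.21 ± 0.25 (limma adjusted p = 0.000208), and its log2 difference of -2.62 was -3.96 with those signals. Z00005948-1 (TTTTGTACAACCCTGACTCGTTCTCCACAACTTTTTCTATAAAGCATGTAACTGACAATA) was 5.51-fold lower, at -4.47 ± 0.27 against -2.01 ± 0.18 (limma adjusted p = 0.000596). In all, 243 probes were higher and 179 lower by limma's moderated test, with median folds of 1.58 and 1.62. The replicate block called 2150 probes, a fit on the 4 arrays of this stage 2985, and leaving out knockout replicate 2 of this stage gave 120, while the balance turned without wild-type replicate 1 (64 higher, 96 lower). Median centring called 363 higher and 84 lower, and with Agilent's processed signals Z00056369-1 missed the threshold with a log2 difference of 2.58, as before (limma adjusted p = 0.0907, the highest of its alternatives, which began at 3.69e-06), while Cy3 alone gave 1.98.

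Averaged over the 3 stages, Z00008117-1 and Z00068163-1 were the most reduced of the named probes and Z00056369-1 and Z00011465-1 the most raised. Z00008117-1 was lower by 2.70 ± 0.08 (SE) on the log2 scale, with knockout below wild type at every stage (limma adjusted p = 1.35e-07), and 4 of its 6 knockout arrays were well above background. Z00068163-1 had a log2 difference of -2.16 ± 0.13 (limma adjusted p = 6.41e-06), also with 4 of 6 knockout arrays above background. Z00056369-1 was 3.05-fold higher in knockout (log2 difference 1.61 ± 0.12, limma adjusted p = 3.54e-05). Z00011465-1 (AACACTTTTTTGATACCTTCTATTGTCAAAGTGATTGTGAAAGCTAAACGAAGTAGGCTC) was 2.64-fold higher (1.40 ± 0.05, limma adjusted p = 6.17e-07). With Agilent's processed signals the differences were -3.37 for Z00008117-1, -3.31 for Z00068163-1 and 2.36 for Z00056369-1. In all, 1360 probes were higher and 1584 lower by limma's moderated test, with median folds of 1.23 and 1.26, and 300 of them (51 higher, 249 lower) differed by at least 1.5-fold. The replicate block called 6704 probes, with the balance turned (3703 higher, 3001 lower), as it was without E15.5 knockout replicate 1 (3110 higher, 2612 lower), and Agilent's processed signals called 1556. The same test on the reference channel, which held the same RNA on every array, called 104 probes, and limma called 0 of 60 control probes in the footpad ratio, with 1 at an unadjusted p under 0.05.

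**Figure D2:**
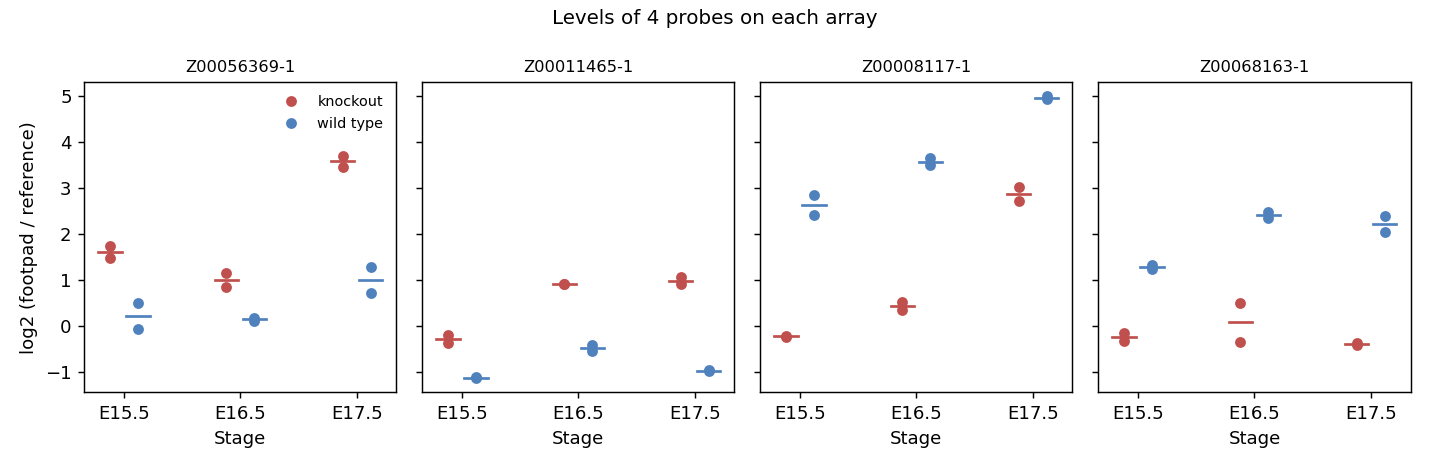
Log2 ratio of footpad over reference (y axis) at each stage (x axis) for the 4 probes named in the average over stages, with knockout arrays in red and wild-type arrays in blue, points for single arrays and lines for group means. Z00011465-1 lay at 0.91 and 1.06 in the E17.5 knockout and at -0.99 and -0.98 in wild type, and Z00008117-1 lay lower in knockout at every stage.

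The stages shared more calls than independent lists of the same sizes would. Of the probes lower in knockout, E15.5 and E16.5 shared 246 (13.0 expected), E16.5 and E17.5 shared 90 (2.6 expected) and E15.5 and E17.5 shared 72 (5.2 expected). Of the probes higher in knockout the same comparisons shared 39 (4.1 expected), 53 (1.1 expected) and 36 (7.3 expected). No array served in more than 1 stage. All stages were tested with a shared estimate of each probe's spread, however, so a probe with a small spread is favoured at each stage. The expected counts ignore this, and part of the excess may follow from it. At all 3 stages 86 probes were called, 60 of them lower each time and 24 higher each time. Across probes, which are not independent replicates, knockout differences correlated at 0.29 between E15.5 and E16.5, 0.54 between E16.5 and E17.5 and 0.12 between E15.5 and E17.5, with rank correlations of 0.13, 0.51 and 0.05. Calls in opposite directions numbered 3 between E15.5 and E16.5, 3 between E16.5 and E17.5 and 15 between E15.5 and E17.5.

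**Figure D3:**
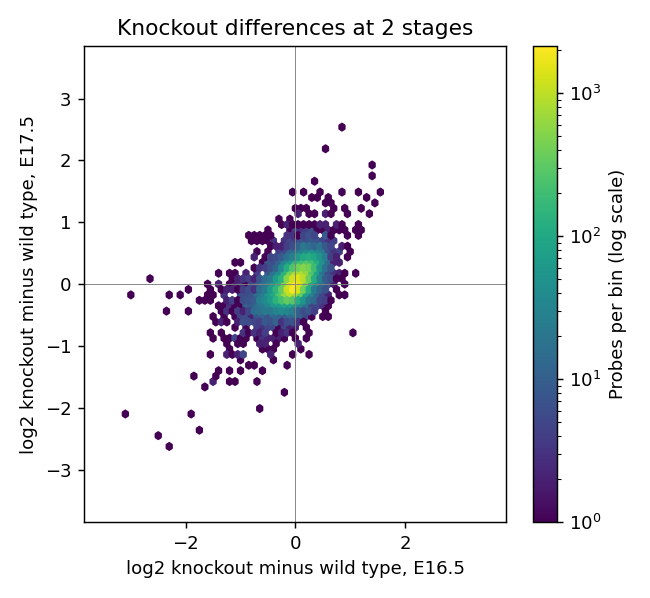
Log2 difference of knockout minus wild type at E16.5 (x axis) and at E17.5 (y axis) for the probes tested, as hexagonal bins coloured by the number of probes on a log scale. The differences correlated at 0.54 across probes.

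The knockout difference itself changed with stage for a smaller set of probes. Z00025150-1 (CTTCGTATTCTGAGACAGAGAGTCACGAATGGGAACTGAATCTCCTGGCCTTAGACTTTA) was lower in knockout at E15.5 by 2.28-fold and higher at E17.5 by 2.17-fold (limma adjusted p of the difference between stages = 0.00928). Z00023605-1 differed by 0.24 on the log2 scale at E15.5 and by 2.21 at E17.5 (limma adjusted p of the difference between stages = 0.000422). Z00046795-1 (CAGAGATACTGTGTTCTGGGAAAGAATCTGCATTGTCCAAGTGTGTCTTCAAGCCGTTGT) moved from 0.25 at E15.5 to -2.05 at E17.5 (limma adjusted p of the difference between stages = 0.000422). Z00024962-1 (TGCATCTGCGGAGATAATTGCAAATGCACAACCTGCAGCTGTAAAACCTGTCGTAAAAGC), not well above background on any E15.5 array, was 3.37-fold lower in knockout at E17.5 (limma adjusted p of the difference between stages = 0.0029), and no size is given for its change from E15.5. In all, 88 probes passed limma's F test. Estimates of 65 of them had opposite signs at E15.5 and E17.5, whether or not either difference was called. Among all probes tested, 15 were called in opposite directions at these stages. The difference of the 88 probes was largest at E15.5 for 37, at E16.5 for 9 and at E17.5 for 42. The replicate block called 3857 probes and Agilent's processed signals 0, with 4302 at an unadjusted p under 0.05 in limma. With Agilent's processed signals the change from E15.5 to E17.5 was 1.28 against 2.31 for Z00025150-1 (limma adjusted p = 0.315), -0.92 against -2.30 for Z00046795-1 (0.22) and 2.71 against 1.96 for Z00023605-1 (0.071), and Z00024962-1 was not called either (0.393), the highest adjusted p of each probe's alternatives, which began at 0.00209, 0.00014, 0.000175 and 0.00115. With the authors' processed values Z00046795-1 (-0.92, limma adjusted p = 0.187) and Z00024962-1 (limma adjusted p = 0.385) missed the threshold too, while Cy3 alone gave -3.86 for Z00046795-1, and Z00025150-1 was not called without E17.5 knockout replicate 1 (limma adjusted p = 0.0589) or 2 (0.0681). Leaving out a single array gave from 7 (without E17.5 knockout replicate 2) to 4257 (without E15.5 knockout replicate 1).

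In wild-type footpad skin, Z00028697-1 rose from a log2 ratio of 2.80 ± 1.43 (SD, n = 2) at E15.5 to 9.19 ± 0.11 at E17.5 (limma adjusted p = 3.36e-06), a log2 difference of 6.39 that was 7.40 without E15.5 wild-type replicate 1 and 5.37 without replicate 2. Z00037703-1 (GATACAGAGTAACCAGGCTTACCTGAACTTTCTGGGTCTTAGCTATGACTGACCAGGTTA), not well above background at E15.5, was higher at E17.5, at 4.40 ± 0.25 (limma adjusted p = 7.9e-09), and no fold is given against its E15.5 level. Z00047077-1 (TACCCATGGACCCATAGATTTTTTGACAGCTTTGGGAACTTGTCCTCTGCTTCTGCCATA) fell 47.8-fold, from 7.51 ± 0.61 to 1.93 ± 0.20 (limma adjusted p = 1.16e-06), a log2 difference of -5.58 that was -4.55 with Agilent's processed signals and -4.78 with median centring. Z00026015-1 (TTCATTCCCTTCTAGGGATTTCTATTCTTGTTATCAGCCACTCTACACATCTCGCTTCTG) fell 42.3-fold, from 5.94 ± 0.60 to 0.54 ± 0.61, with 1 of 2 arrays above background at E17.5 (limma adjusted p = 9.14e-06), a log2 difference of -5.40 that ran from -6.50 with the authors' processed values to -4.16 with median centring. In all, 6385 probes were higher and 6726 lower at E17.5 by limma's moderated test, 43.2% of those tested. Between E15.5 and E16.5 the count was 13225, and between E16.5 and E17.5 it was 2174. Each stage lay on a slide of its own, so stage and slide cannot be told apart, and the balance turned with median centring (6340 higher, 4195 lower) and with Agilent's processed signals (6525 higher, 6242 lower). In the reference channel, which held the same RNA on every array, limma called 1024 probes in this contrast (752 higher, 272 lower). Whether the slide or Cy3 signal in that channel gave these calls was not tested.

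Probes were also grouped by their change over the other stages. The 303 probes that rose at least 2-fold from E16.5 to E17.5, averaged over genotypes, had a median log2 difference of -0.39 relative to all probes in the E15.5 knockout. Of these, 101 were called lower and 2 higher at E15.5. The class's shift passed camera (adjusted p = 3.23e-27) and missed the threshold with an estimated correlation (adjusted p = 0.104 with an estimated correlation), while fry, which asks whether the probes move on balance in a shared direction and compares them with no others, gave an adjusted p = 0.00666. Its median level lay -0.16 and -0.23 from the stage mean on the knockout arrays, and 0.30 and 0.09 from it on the wild-type arrays. The 128 probes that fell from E16.5 to E17.5 had 5 called higher and 5 called lower at E15.5, with a median of -0.11 relative to all probes (camera adjusted p = 0.0448, adjusted p = 0.626 with an estimated correlation, and fry adjusted p = 0.527). Among 2010 probes at least 4-fold over the reference, 409 were lower and 101 higher in knockout averaged over stages, with a median log2 difference of -0.05 relative to all probes (camera adjusted p = 1.27e-05, adjusted p = 0.104 with an estimated correlation, and fry adjusted p = 0.00666). In this class 324 were lower and 124 higher at E15.5 and 138 lower and 25 higher at E16.5, but 23 lower and 36 higher at E17.5 (camera adjusted p = 0.00399 for a downward shift, adjusted p = 0.19 with an estimated correlation, and fry adjusted p = 0.141).

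**Figure D4:**
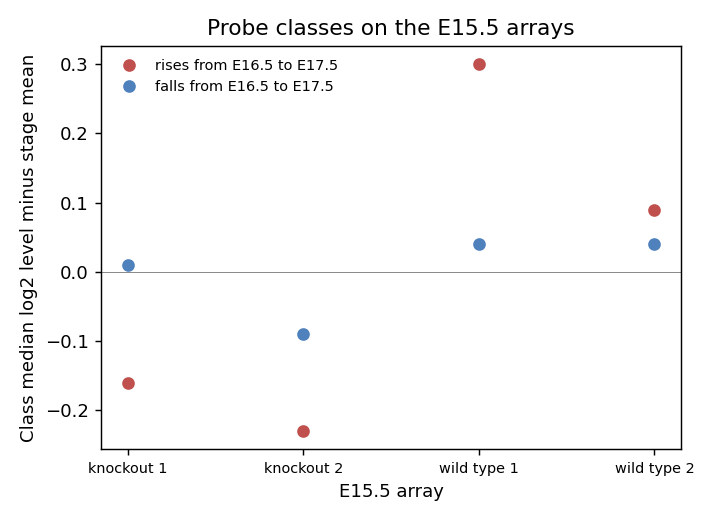
Median log2 level of the probes that rise (red) and fall (blue) from E16.5 to E17.5, as a difference from the mean of the 4 arrays (y axis), on each E15.5 array (x axis). The rising class lies at -0.16 and -0.23 on knockout arrays and at 0.30 and 0.09 on wild-type arrays.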

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

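Tests on single arrays, on probe GC content and on the falling class were chosen after the result was seen, while the test on normalization was set before. The knockout difference of 7 named probes differed between stages in limma's F test. Z00023605-1, Z00046795-1, Z00024962-1 and Z00025150-1 were named because they passed this test, so for them it is no separate evidence. Z00051506-1 was named for its knockout difference at E15.5, and Z00037703-1 for its wild-type change from E15.5 to E17.5. Both values are terms of the tested difference, so the test is not fully separate evidence for these probes either. The adjusted p was 0.000422 for Z00023605-1 and for Z00046795-1, 0.0029 for Z00024962-1, 0.00428 for Z00051506-1, 0.00928 for Z00025150-1, 0.018 for Z00011465-1 and 0.0424 for Z00037703-1, and Z00024962-1 and Z00037703-1 were not well above background on any E15.5 array, so no size is given for their change from that stage. Groups of 2 arrays are too small for a test of single outlying samples.

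The class that rises from E16.5 to E17.5 was lower in knockout at E15.5 by camera (adjusted p = 0.104 with an estimated correlation), and its knockout difference at E17.5 against E15.5, which holds the E15.5 shift as a term, was shifted upward by camera (p = 1.12e-23) but not past the threshold with an estimated correlation (adjusted p = 0.104, and fry adjusted p = 0.00896). No single E15.5 array accounted for it, since its median of -0.39 relative to all probes was -0.30 at its weakest, without wild-type replicate 1, and neither did normalization (-0.33 at its weakest, with Cy3 alone) or probe GC content (-0.38 after the correction). A candidate explanation is that knockout skin was less advanced at E15.5. It would raise the probes that fall from E16.5 to E17.5 if these also fall from E15.5 to E16.5, which was not tested. Their median was -0.11, on the other side of 0 from that prediction. This shift passed camera (adjusted p = 0.0448) and not the test with an estimated correlation (adjusted p = 0.626). Without the behaviour of these probes from E15.5 to E16.5, the value does not decide the question. Some other values go with less advanced knockout skin. E15.5 knockout arrays lay farther from the later stages on the leading component (-71.8 and -85.7, against -43.5 and -58.7 in wild type). These are the arrays that gave the class shift, so the component is not separate evidence. At E16.5, 182 of 1392 probes rising over time were called lower and 7 higher (adjusted p = 0.327 with an estimated correlation, and fry adjusted p = 0.102). The 1542 probes falling over time, which less advanced skin would raise, had 11 called higher and 11 lower at E16.5. Their median log2 difference was -0.046 (adjusted p = 0.656 with an estimated correlation, and fry adjusted p = 0.527). At E17.5, 626 probes rising from E15.5 to E16.5 had 7 called higher and 2 lower, with a median of 0.07 (camera adjusted p = 0.656 with an estimated correlation). The 1888 probes falling between those stages had 16 called higher and 5 lower, with a median of 0.099 (camera adjusted p = 0.4 with an estimated correlation). The hypothesis stays open. Position on the slide was checked through the reference channel alone, where limma called 1 probe at E15.5, and differences in litter or exact age were not tested.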

How the results depend on the processing

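The correction for probe GC content was chosen after seeing the data. Of the values of named probes under the alternatives other than Aquantile scaling, none reversed and 22 lost the threshold, 7 with Agilent's processed signals, 5 with the authors' processed values, 4 in the fit on E15.5 arrays alone and 6 with an array left out. Counts below are in the order E15.5, E16.5, E17.5, average, difference between stages, and the cause of each move was not tested unless given. The replicate block raised them to 6909, 2378, 2150, 6704 and 3857, and with the GC correction as well to 7040, 2245, 1644, 6173 and 3895, and changed no other call. Agilent's processed signals gave 681, 144, 174, 1556 and 0. The authors' processed values gave 578, 143, 183, 1378 and 10, and 8444 for the wild-type time course, over fewer probes (18782). The 1.5-fold minimum gave 800, 354, 274 and 300, and 6468 for the time course, by its construction. Array weights gave 243 at E15.5, 1096 at E16.5, 2924 at E17.5 and 43 for the difference between stages. Fits on the arrays of a stage alone gave 0 at E15.5 and 2985 at E17.5. Median centring gave 208 at E16.5 and 1421 for the average. Requiring all 12 arrays above background gave 269 at E17.5 and 30 for the difference between stages, for which an offset of 16 gave 44 and Cy3 alone 45. The reference channel gave 104 for the average and 1024 for the time course. Aquantile scaling left log ratios as they were by its construction and tests nothing. With an estimated correlation the medians of -0.39 for the class rising later at E15.5 and -0.046 for the probes above the reference were past no threshold after adjustment.

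With an array left out, the lone sample is assumed to vary like the other groups. The E15.5 count ran from 135 (without E15.5 wild-type replicate 1) to 7809 (without E15.5 knockout replicate 1), with 566 without E15.5 knockout replicate 2, 1002 without either E16.5 knockout, and 837 or 942 without an E17.5 knockout or wild type. The E16.5 count ran from 115 (without E16.5 knockout replicate 2) to 1173 (without either E15.5 knockout), with 294 and 194 without replicate 1 of E16.5 knockout and wild type, and 324 or 340 without an E17.5 knockout or wild type. The E17.5 count ran from 120 (without E17.5 knockout replicate 2) to 811 (without either E15.5 knockout), with 199, 160 and 187 without E17.5 knockout replicate 1 and wild-type replicates 1 and 2. The average ran from 1358 (without E17.5 knockout replicate 2) to 5722 (without E15.5 knockout replicate 1), with 1705 without E15.5 wild-type replicate 1, 1420 without E16.5 knockout replicate 2, 1763 without E16.5 wild-type replicate 1, and 1902, 1399 and 1755 without E17.5 knockout replicate 1 and wild-type replicates 1 and 2. The difference between stages ran from 7 (without E17.5 knockout replicate 2) to 4257 (without E15.5 knockout replicate 1), with 36 and 160 without E15.5 wild-type replicates 1 and 2, 45 and 33 without E16.5 knockout replicates 1 and 2, 22 without E17.5 knockout replicate 1, and 17 and 9 without E17.5 wild-type replicates 1 and 2. The time course ran from 8800 to 14745, the class median at E15.5 from -0.50 to -0.30 and that of the probes above the reference from -0.06 to -0.04.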

Other observations

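Tests of probe GC content and of the reference channel's calls were chosen after the result was seen, while the splits and the correlation within the reference channel were set before. Of 1451 probes at least 4-fold below the reference, 128 were called higher and 34 lower in knockout averaged over stages (camera adjusted p = 6.04e-07, adjusted p = 0.327 with an estimated correlation, and fry adjusted p = 0.0702). That balance of calls held at E15.5 (112 higher, 8 lower, camera adjusted p = 1.88e-06, adjusted p = 0.327 with an estimated correlation, and fry adjusted p = 0.0702). It did not hold at E16.5 (6 higher, 12 lower, camera adjusted p = 0.0896) or E17.5 (13 higher, 21 lower, camera adjusted p = 0.00114 for an upward shift, and adjusted p = 0.502 with an estimated correlation). At E16.5, 1392 probes rising from E15.5 to E17.5 had 182 called lower and 7 called higher (camera adjusted p = 1.77e-12, adjusted p = 0.327 with an estimated correlation, and fry adjusted p = 0.102). The 1542 probes falling from E15.5 to E17.5 had 11 called higher and 11 lower, with a median log2 difference of -0.046 (camera adjusted p = 0.128, adjusted p = 0.656 with an estimated correlation, and fry adjusted p = 0.527).

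The count averaged over stages was set against splits that keep 2 arrays of each stage on each side. Of 100 splits drawn from the 108 possible, 1, the real one, gave as many as 2944 calls, and the highest of the others gave 757. The real split thus stood out among those drawn. Most other splits mix the genotypes within a group, which raises the spread and lowers their counts by construction. Arrays of a group may also be technical replicates, so the splits cannot exclude differences between animals or litters. Among the 28 splits that part all 6 same-numbered pairs, as the real split does, the highest other gave 452, and the remaining splits leave some pairs together. For the probes above the reference, 2 of the 100 splits gave a camera p as small as 4.77e-06, with 7.3e-07 in the other, and among the splits parting all pairs only the real one did. Splits with 0 calls also gave camera p-values of 7.59e-06 and 4.04e-05, so camera at the preset correlation gave small p-values in arbitrary splits too. The class was chosen after seeing the data and had a camera adjusted p = 0.104 with an estimated correlation. The splits therefore do not exclude chance assignment for this class.

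The knockout differences at E16.5 and E17.5 correlated at 0.54 across probes. After the correction for probe GC content the correlation was 0.52, which argues against GC content as the cause. Between the same array positions the reference channel gave 0.19. That channel shows only position effects that reach Cy5, and noise lowers its correlation, so position is not excluded as the whole cause. A shared effect of the genotype stays open, along with position itself and other differences that follow it on every slide.

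The reference channel held the same RNA on every array, yet 104 probes differed in it between knockout and wild-type arrays. These probes had a median log2 ratio of footpad over reference 2.97 above that of other probes, and 82.7% moved in the same direction as the footpad ratio. Cy3 signal reaching the Cy5 channel at probes bright in footpad RNA would give both values. The shared direction does not exclude position, since the knockout difference of the footpad ratio lies between the same array positions. A leak of Cy3 signal would reduce the folds of those probes.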
